A study of Mus musculus with 10 samples.

How the data were processed

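RNA was measured in whole hearts of 10 mice, 5 per group, by sequencing of total RNA libraries made from 1 μg of RNA with the VAHTS Universal V10 kit, per the labels' protocols. All animals had the same genotype, labelled MCM with Chmp4bF/F. One group (cKO) was given tamoxifen at 0.1 mg/g under the skin over 2 days from postnatal day 0, the other (control) was given corn oil, and hearts were taken at postnatal day 10. Groups and replicate numbers were taken from the sample titles.

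The authors deposited 1 table of TPM (transcripts per 1000000), which divides read counts by gene length and closes each library to a total of 1000000. Tools named in the submitters' processing notes, with no role or order, were bcl2fastq, Trimmomatic 0.32, FastQC 0.11.7, STAR 2.7.1, Picard 1.96, HTSeq 0.11.2 and DESeq2 1.22.2, with build mm10. The annotation release, the gene lengths and the strand setting were not given in the sources used here, so antisense and overlapping genes could not be told apart. TPM keeps no depth, so the number of reads behind each value is unknown and no counting interval was given. The table held 55858 genes, of which 51460 (92.1%) matched GENCODE M21 by gene ID without its version and 35 with its version. Coordinates are those of GENCODE M21 on GRCm38, the assembly also called mm10. No pair of libraries held identical values.

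Values were tested as log2(TPM + 1), so that fold changes of genes with low values are understated. Genes with a TPM of at least 1 in at least 5 of the 10 libraries were kept (13282 genes). Groups were compared with limma 3.58.1 in R 4.3.3 (linear model, moderated variance with a mean-variance trend, two-sided), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Single values were compared by a two-sided exact permutation test over all 252 splits of the libraries into 5 and 5, for which the smallest possible p is 0.00794. Recovery was simulated from values scaled as described below, with independent noise for each gene. Of 13282 genes, 67, 67 and 66 were changed by 1.5-fold, 2-fold and 4-fold. Limma recovered 59.7%, 91.0% and 95.5% of them, with 8 false calls among 172. Neither TPM as deposited nor the many calls of the real comparison were simulated, so these rates do not describe them. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

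Because TPM is a share of a fixed total, values were also divided by a median-of-ratios size factor per library, computed from 16393 genes. Results from these scaled values are given as relative to the median gene. They measure a gene against the other genes and cannot show a change in total RNA per cell.

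Before the data were examined, 23 gene lists and 14 marker lists were fixed, and 641 of their 642 members were matched. The gene lists covered the ESCRT machinery, T-tubule and dyad structure, calcium handling, cardiac ion channels, the sarcomere, fetal and stress genes, the intercalated disc, membrane repair, autophagy, the lysosome, the ATF4 response, endoplasmic reticulum chaperones, p53 targets, inflammatory mediators, the interferon response, extracellular matrix, immediate early genes, mitotic cell cycle, DNA replication, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, fatty acid oxidation and glycolysis. The marker lists covered fibroblasts, endothelial cells, macrophages, lymphocytes and thymus, neutrophils, smooth muscle and pericytes, epicardium, atrial cardiomyocytes, erythroid cells, fat, lung epithelium, skeletal muscle, Schwann cells and neurons, and sex-linked genes. Some genes stand in more than 1 list (for example Nppa, Myl7, Dysf, Kcnj3 and Gja1). The 31 lists with at least 3 tested genes were tested with camera (preset correlation of 0.01), with Benjamini-Hochberg adjustment over the 31. Camera with an estimated correlation, and fry, were run as alternatives. Camera and fry values are from TPM as deposited unless given as relative to the median gene.

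Genes named with values were chosen by a rule fixed in advance. They were Chmp4b, the 10 largest rises and 10 largest falls among called genes with a mean TPM of at least 5 in either group and no overlap between groups (predicted gene models and pseudogenes were counted but not named), and up to 4 of the most significant members of each called gene list and of the T-tubule, calcium and ESCRT lists (up to 2 for marker lists). Not every gene that the rule selects is reported here. Any other gene named was chosen after its values were seen, and this is said where it appears. Settings varied by choice made in advance were the pseudocount, filters, scalings, variance models, library weights, a Ddx3y covariate and leaving out each library. Settings added after seeing the data were TPM over nuclear protein-coding genes, TPM without the 100 most abundant genes, leaving out 3 cKO libraries with Xist, and the settings chosen in advance repeated relative to the median gene.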

Results

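Gene expression was measured in hearts of 10-day-old mice, in 5 cKO and 5 control animals. Chmp4b encodes a subunit of ESCRT-III, the membrane-cutting complex of endosomes, cell division and membrane repair, and the series concerns the part played by ESCRT in forming T-tubules, the membrane folds that carry the action potential into heart muscle cells. The cKO animals were given tamoxifen to delete Chmp4b, and the controls were given corn oil. Each library summed to 1000000 TPM, and its read depth is unknown. Between 13578 and 14011 genes reached 1 TPM in the cKO libraries, and between 12354 and 12753 in the control libraries.

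Chmp4b (ENSMUSG00000038467.16, a protein-coding gene on the plus strand of chromosome 2 from 154651705 to 154694785 in GRCm38) was lower in cKO hearts. Its TPM was 38.2 ± 1.42 (SD, n = 5) in cKO and 47.4 ± 8.61 (SD, n = 5) in control hearts, a log2 difference of -0.29 (exact permutation p = 0.0476). The groups overlapped as deposited, with control replicate 4 at 36.6. Relative to the median gene the values were 29.3 ± 1.37 in cKO and 60.5 ± 6.47 in control (SD, n = 5), without overlap, a ratio of 0.485 (exact permutation p = 0.00794, the smallest this design allows). As deposited, the log2 difference was -0.27 to -0.30 without any 1 cKO library and -0.21 to -0.28 without control replicate 6, 8 or 9, with the exact permutation p between 0.0556 and 0.0952, so the call was lost with fewer libraries. It was -0.38 (exact permutation p = 0.00794) without control replicate 4 and -0.33 (exact permutation p = 0.0476) without control replicate 13. Values are summed over the whole gene and over all cell types of the heart, and which part of the gene is deleted was not given in the sources used here.

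**Figure D1:**
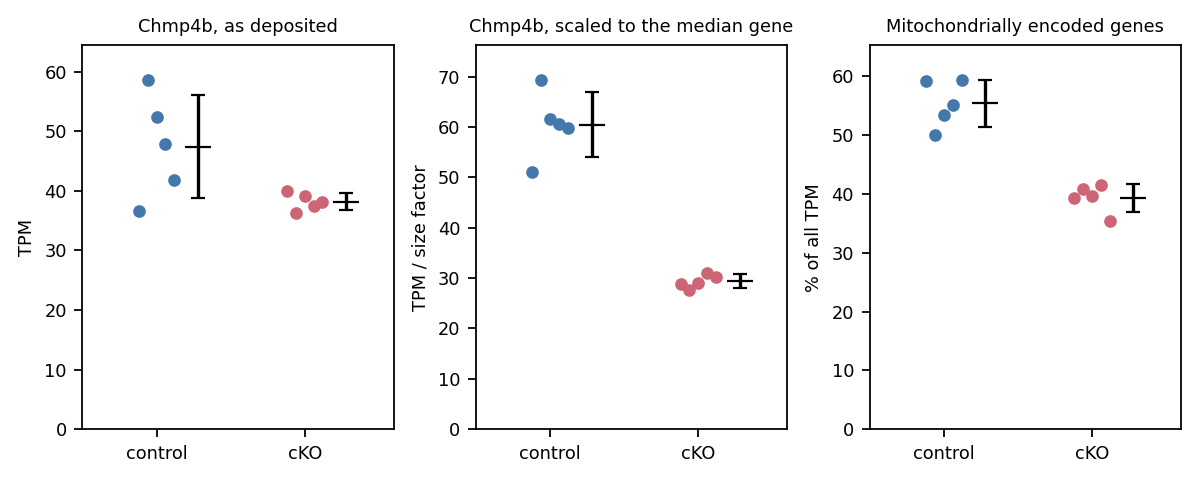
Chmp4b TPM as deposited (left), Chmp4b TPM divided by the size factor (middle) and the percentage of all TPM on mitochondrially encoded genes (right), with 1 point per library and the mean ± SD of 5 libraries beside the points. Scaled Chmp4b and the mitochondrial share did not overlap between groups, while Chmp4b as deposited did, with control replicate 4 at 36.6.

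In cKO hearts, the glutathione transferase genes Gsta1, Gsta2 and Gsta3, the keratin genes Krt8 and Krt18, the stress hormone gene Nppa and the autophagy receptor gene Sqstm1 rose. After scaling, 22 of 27 lysosome, 16 of 20 interferon response, 19 of 27 extracellular matrix and 17 of 17 macrophage genes rose, and 1 lysosome gene fell relative to the median gene. On the same scale, 15 of 18 calcium handling, 14 of 21 ion channel, 18 of 20 sarcomere, 23 of 27 fatty acid oxidation and 26 of 26 nuclear-encoded oxidative phosphorylation genes fell, and 2 fatty acid oxidation genes rose. Camera called each of these 9 lists with its preset correlation and none of them with an estimated correlation (adjusted p from 0.0732 to 0.182 with an estimated correlation, relative to the median gene). Mitochondrially encoded transcripts made up 39.4% ± 2.34 of all TPM in cKO and 55.4% ± 3.96 in control hearts (SD, n = 5, exact permutation p = 0.00794). Nuclear protein-coding genes correspondingly took 52.4% ± 2.29 and 35.6% ± 3.98. The single gene mt-Atp8 held 9.6% to 14.6% of TPM in cKO and 14.0% to 23.0% in control libraries, with overlap. TPM divides by gene length, so these are not shares of reads. As deposited, limma called 10620 of 13282 genes at an adjusted p under 0.05, 10160 higher and 460 lower in cKO, and 2317 of them changed by at least 2-fold (2239 higher and 78 lower).

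The median of all tested genes lay 0.63 above 0 on the log2 scale as deposited. Relative to the median gene, limma called 5529 genes, 2763 higher and 2766 lower, of which 832 changed by at least 2-fold (426 higher and 406 lower). The same 2763 genes rose and the same 460 genes fell in both, 797 genes were higher as deposited but lower relative to the median gene, and 6600 were called higher only as deposited. Counts within the gene and marker lists are to be read against these counts over all 13282 tested genes. The values of 4163 genes did not overlap between groups after scaling, where chance gives 0.794% of genes. The first principal component held 72.4% of the variance as deposited and 53.7% after scaling.

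**Figure D2:**
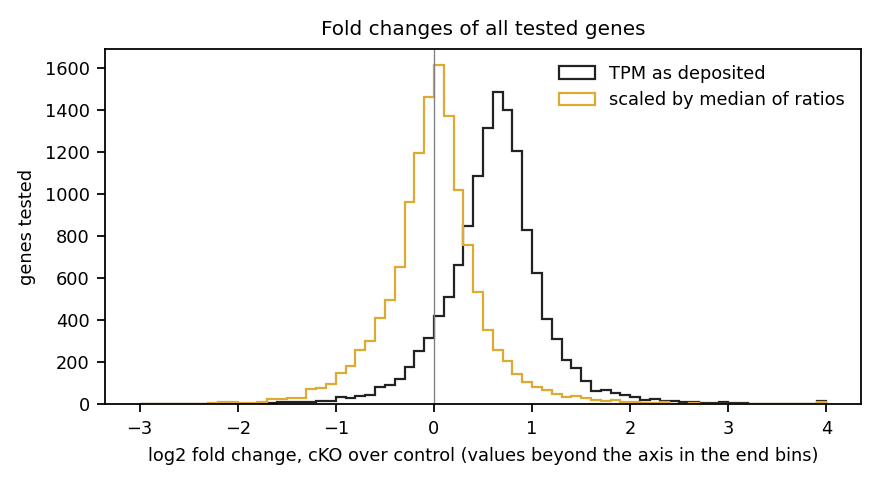
Number of tested genes by log2 fold change of cKO over control, from TPM as deposited and after scaling by median of ratios, for 13282 genes. The median lies at 0.63 as deposited and at 0.01 after scaling.

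The 10 largest rises among named genes took in 3 genes for glutathione transferases, which join glutathione to reactive compounds, and Krt18 and Krt8, which encode keratins of simple epithelia. Gsta2 rose from 0.144 ± 0.122 to 87.1 ± 41.8 TPM (log2 fold change 6.16 ± 0.24 SE), Gsta1 from 0.258 to 54.5 TPM (5.43) and Gsta3 from 0.478 to 33.6 TPM (4.53). Gsta1 and Gsta2 are close copies, so the split of reads between them is uncertain. Krt18 rose from 3.37 ± 0.379 to 192 ± 41.9 TPM and its partner Krt8 from 0.955 ± 0.177 to 74.0 ± 12.7 TPM (log2 fold changes 5.44 and 5.25, limma adjusted p = 4.24e-11 for each). Nppa, the atrial natriuretic peptide gene, rose from 118 ± 39.1 to 3153 ± 1042 TPM (log2 fold change 4.74). The others were Sprr1a (log2 fold change 4.76), Mlana (4.74), Lgals3, which encodes galectin-3 (4.14), and Uchl1, a ubiquitin hydrolase gene (4.11). The largest falls were in Mylk4, a myosin light chain kinase gene, from 19.3 ± 3.37 to 2.86 ± 0.970 TPM (log2 fold change -2.41 ± 0.16 SE), Clec3b (-1.84), Lrtm1 (-1.83), the striated muscle ribosomal protein gene Rpl3l (-1.80) and the mitochondrial creatine kinase gene Ckmt2 (-1.77). Asb15 (-1.70), the nuclear receptor gene Nr4a3 (-1.64), the water channel gene Aqp4 (-1.62), Hrc (-1.60) and Fitm1 (-1.58) followed. All 20 kept their direction and call in every alternative run, and 1 predicted gene model in each direction ranked among them.

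**Figure D3:**
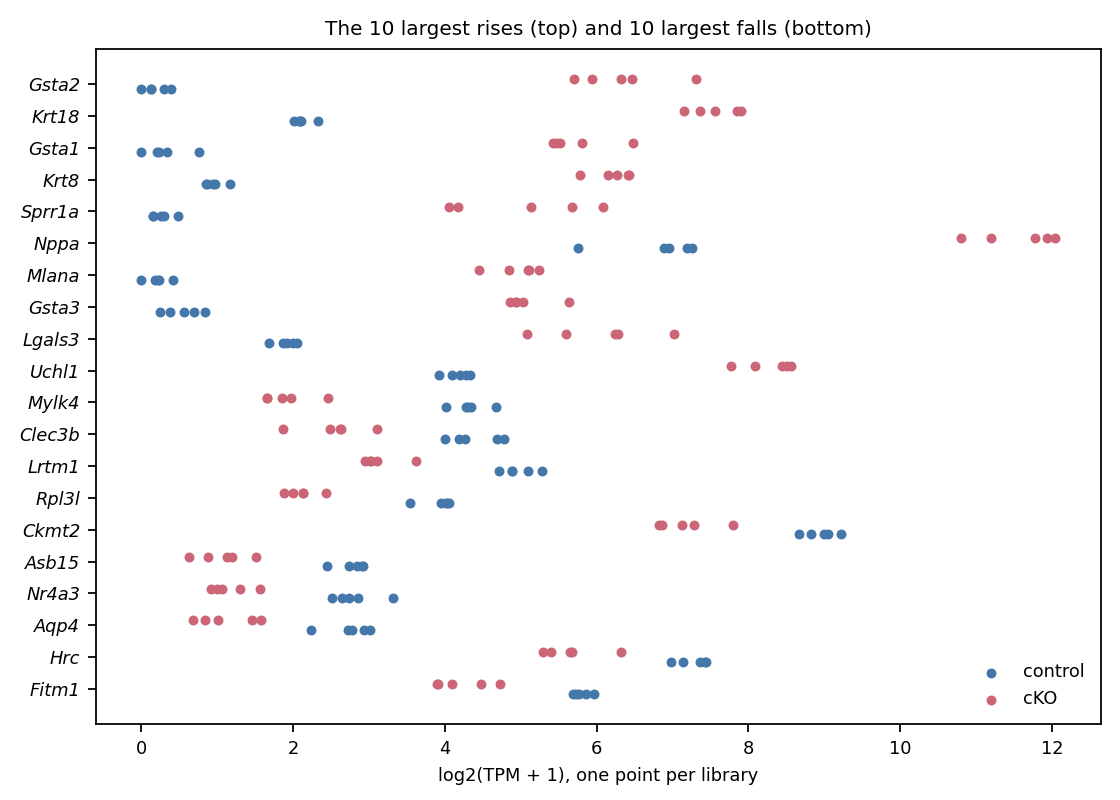
Log2(TPM + 1) in each library for the 10 largest rises and the 10 largest falls, with 5 points per group. No gene shown has overlapping groups, and Krt18 averages 192 TPM in cKO and 3.37 TPM in control hearts.

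Genes of the T-tubule and dyad, the junction of T-tubule and sarcoplasmic reticulum, were lower relative to the median gene in 15 of 20 tested members, higher in 0 and not called in 5 (16 called adjusted over the list alone). As deposited, 7 rose, 2 fell and 11 were not called (9 adjusted over the list alone), with a median of 0.14. On that scale camera still placed the list below other genes (adjusted p = 0.000306; adjusted p = 0.515 with an estimated correlation). Relative to the median gene, camera gave it an adjusted p = 3.16e-08, and an adjusted p = 0.0732 with an estimated correlation. Tcap, encoding a titin-capping protein, fell from 242 ± 21.5 to 127 ± 35.0 TPM, and by 1.70 on the log2 scale relative to the median gene. Nexn, Dnm2 and Cavin1 rose as deposited (log2 fold changes 0.71, 0.60 and 0.48) but stood at -0.03, -0.12 and -0.25 relative to the median gene, where limma called Cavin1 alone (adjusted p = 0.00441). Among genes chosen after their values were seen, the T-tubule shaping gene Bin1 rose by 0.61 as deposited and stood at -0.05 relative to the median gene (limma adjusted p = 0.691). The dyad tether gene Jph2 had 68.0 ± 8.85 TPM in cKO and 75.1 ± 7.85 in control hearts (limma adjusted p = 0.238), and Cav3 55.9 ± 5.15 and 56.5 ± 6.62 (limma adjusted p = 0.918). Against the median gene they fell by 0.88 and by 0.74. In the same hearts, macrophage markers rose in 17 of 17 members (median 1.54) and endothelial markers fell in 13 of 15 (median -0.55), both relative to the median gene.

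Calcium handling genes fell relative to the median gene in 15 of 18 tested members, with 0 higher and 3 not called (15 adjusted over the list alone). As deposited, 6 rose, 6 fell and 6 were not called (12 adjusted over the list alone). The list as deposited lay below other genes by camera (adjusted p = 1.96e-09; adjusted p = 0.248 with an estimated correlation). The calcium release channel gene Ryr2 fell from 80.9 ± 8.69 to 41.1 ± 5.83 TPM and the sarcoplasmic reticulum gene Hrc from 154 ± 21.0 to 51.6 ± 16.1 TPM. S100a1 rose as deposited (0.97) and stood at 0.23 relative to the median gene, without a call. Ion channel genes fell relative to the median gene in 14 of 21 members, with 0 higher (15 called adjusted over the list alone), while as deposited 4 rose and 6 fell (9 adjusted over the list alone). Camera gave the list as deposited an adjusted p = 1.96e-09, and an adjusted p = 0.169 with an estimated correlation. Kcnd2 fell by 1.52 and Kcnj3 by 1.56 as deposited, and Kcnk3 by 0.82, whereas Kcnh2 rose by 0.74 and stood at 0.02 relative to the median gene. Sarcomere genes fell relative to the median gene in 18 of 20 members (18 adjusted over the list alone). As deposited, 5 rose and 4 fell (8 adjusted over the list alone). The camera test as deposited gave an adjusted p = 7.85e-08, and an adjusted p = 0.285 with an estimated correlation. Tnni3, cardiac troponin I, fell by 0.72 and Myh7b by 0.92 as deposited, while Des and Myom2 rose by 0.75 and 0.96 and stood at 0.01 and 0.22 relative to the median gene, without a call. Beside the falls in these 3 lists, 17 of 17 macrophage markers rose (median 1.54) and 13 of 15 endothelial markers fell (median -0.55) relative to the median gene.

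Of the other ESCRT genes, 29 of 31 rose as deposited (29 adjusted over the list alone), where 10160 of all 13282 tested genes rose. Relative to the median gene, 11 rose, 3 fell and 17 were not called (14 adjusted over the list alone). Of all tested genes, 2763 rose and 2766 fell on that scale. Camera as deposited gave an adjusted p = 0.00651, and an adjusted p = 0.634 with an estimated correlation. Hgs, the first ESCRT adaptor on endosomes, rose from 7.62 ± 1.55 to 26.5 ± 3.50 TPM, and Stam2, Vps37c and Chmp1a rose by 0.48, 0.67 and 0.31 relative to the median gene. Autophagy genes rose as deposited in 25 of 26 members with 1 lower (26 adjusted over the list alone). After scaling, 12 rose and 1 fell relative to the median gene (13 adjusted over the list alone). By camera this list had an adjusted p = 0.0114 as deposited, and an adjusted p = 0.634 with an estimated correlation. Sqstm1, the receptor that binds ubiquitinated cargo, rose from 81.1 ± 8.52 to 885 ± 152 TPM, and Bnip3, Gabarapl1 and Gabarap rose by 1.44, 0.90 and 0.47 relative to the median gene. All 27 tested lysosome genes rose as deposited (27 adjusted over the list alone). Against the median gene, 22 rose and 1 fell (23 adjusted over the list alone). Camera gave the list as deposited an adjusted p = 5.55e-06, and an adjusted p = 0.571 with an estimated correlation. The protease gene Ctsd rose by 2.05, Cd63 by 1.31, Gaa by 0.70 and Ctsa by 0.62 relative to the median gene. In the same hearts 17 of 17 macrophage markers rose.

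Membrane repair and annexin genes rose as deposited in 12 of 15 members (12 adjusted over the list alone). Of these 15, 11 rose and 3 fell relative to the median gene (15 adjusted over the list alone). The camera test as deposited gave an adjusted p = 0.0141, and an adjusted p = 0.634 with an estimated correlation. Anxa4 rose from 10.8 ± 1.33 to 57.0 ± 9.92 TPM and Anxa7 from 24.0 ± 3.98 to 109 ± 17.0 TPM, with Ahnak and S100a11 also higher (1.24 and 0.68 relative to the median gene). Endoplasmic reticulum chaperone genes rose as deposited in 18 of 19 members (18 adjusted over the list alone). Against the median gene, 8 rose and 1 fell (10 adjusted over the list alone), among them Xbp1 (0.57), Pdia4 (0.44) and Pdia3 (0.38). For the chaperone list as deposited camera gave an adjusted p = 0.0101, and an adjusted p = 0.634 with an estimated correlation. Targets of p53 rose as deposited in 19 of 21 members (19 adjusted over the list alone). After scaling, 12 rose and 2 fell relative to the median gene (15 adjusted over the list alone). By camera this list had an adjusted p = 0.0144 as deposited, and an adjusted p = 0.634 with an estimated correlation. The apoptosis gene Bax rose by 0.89, Phlda3 by 1.23, the cell cycle inhibitor gene Cdkn1a by 1.21 and Perp by 0.97 relative to the median gene.

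Interferon response genes rose as deposited in 19 of 20 members (19 adjusted over the list alone) and relative to the median gene in 16, with 0 lower (17 adjusted over the list alone). Camera gave the list as deposited an adjusted p = 0.000513, and an adjusted p = 0.515 with an estimated correlation. Ifit1 rose from 0.354 ± 0.0965 to 11.4 ± 2.95 TPM, Irf7 from 1.71 ± 0.264 to 8.93 ± 1.92 TPM, and Ifit2 and Isg15 by 0.90 and 1.26 relative to the median gene. Extracellular matrix genes rose as deposited in 27 of 27 members (27 adjusted over the list alone) and relative to the median gene in 19, with 0 lower (20 adjusted over the list alone). The camera test as deposited gave an adjusted p = 5.59e-05, and an adjusted p = 0.571 with an estimated correlation. Loxl2, Tgfb2, Postn and Tnc rose by 1.13, 1.09, 0.77 and 1.24 relative to the median gene. Macrophage markers rose in 17 of 17 members in the same hearts, with a median of 1.54 relative to the median gene, beside these lists and those for membrane repair, endoplasmic reticulum chaperones and p53 targets.

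Nuclear-encoded oxidative phosphorylation genes fell relative to the median gene in 26 of 26 members (26 adjusted over the list alone) and as deposited in 9, with 0 higher (8 adjusted over the list alone). By camera this list had an adjusted p = 1.6e-22 as deposited, and an adjusted p = 0.248 with an estimated correlation. Cox6a2 fell from 851 ± 103 to 540 ± 84.8 TPM and Cox7a1 from 607 ± 168 to 311 ± 72.7 TPM, with Uqcrc1 and Sdha at -0.38 and -0.36 as deposited. All 13 mitochondrially encoded genes fell relative to the median gene and 10 as deposited (13 and 10 adjusted over the list alone), the 1 list called with an estimated correlation as well (camera adjusted p = 1.97e-22; adjusted p = 0.0226 with an estimated correlation, and adjusted p = 0.162 relative to the median gene). The respiratory chain genes mt-Nd4, mt-Nd5, mt-Cytb and mt-Nd2 fell by 0.56, 0.60, 0.52 and 0.55 as deposited. Fatty acid oxidation genes fell relative to the median gene in 23 of 27 members with 2 higher (25 adjusted over the list alone). As deposited, 8 fell and 4 rose (12 adjusted over the list alone). Camera gave the list as deposited an adjusted p = 3.82e-13, and an adjusted p = 0.285 with an estimated correlation. Acaa2 and Etfb fell by 0.63 and 0.49 as deposited. Angptl4 and Pdk4, which restrain lipid uptake and glucose oxidation, rose by 2.11 and 1.28. Macrophage markers rose in 17 of 17 members in these hearts (median 1.54) and endothelial markers fell in 13 of 15 (median -0.55), both relative to the median gene.

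**Figure D4:**
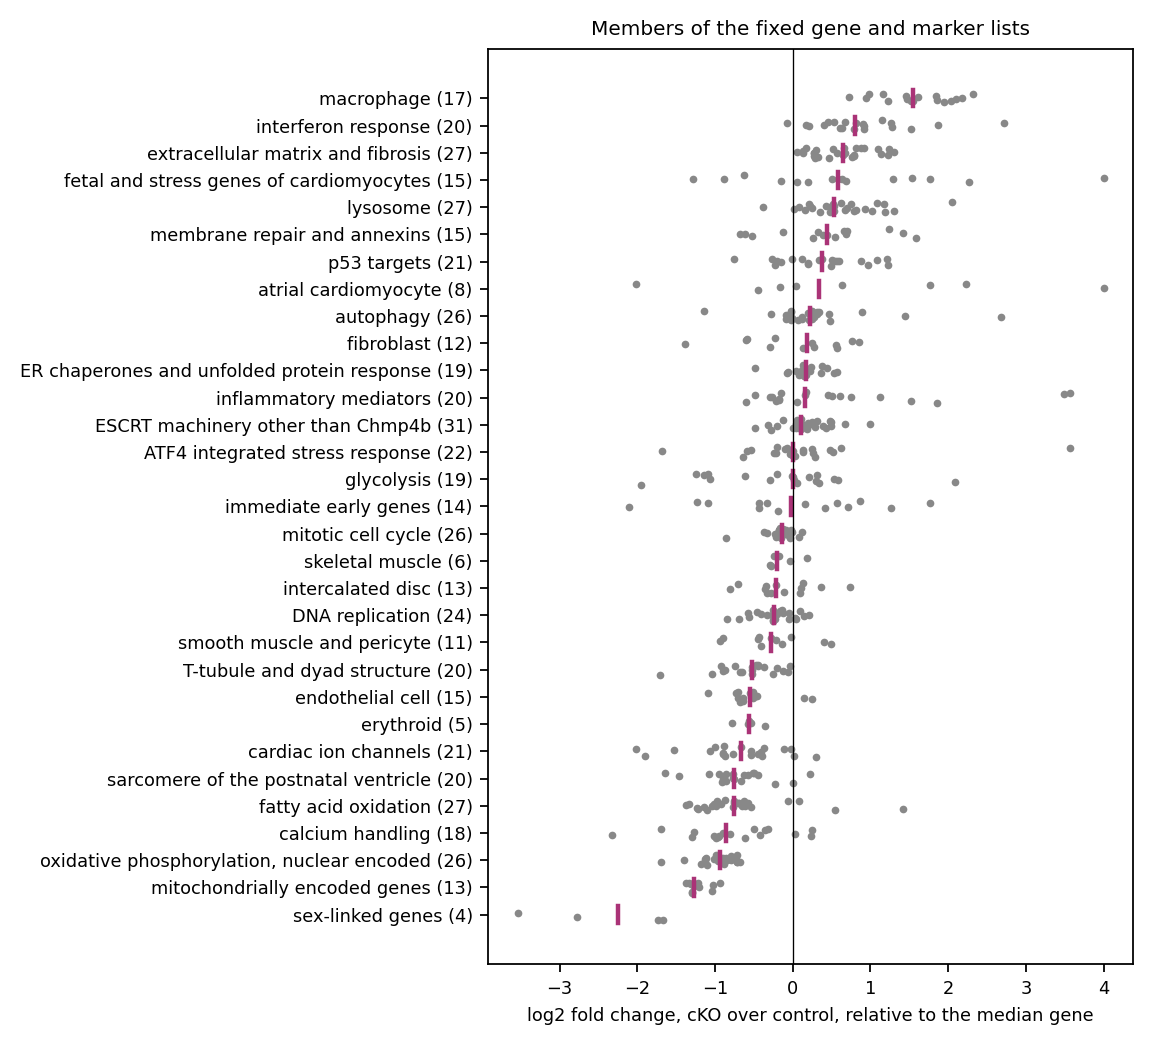
Log2 fold change of cKO over control relative to the median gene for the tested members of each list with at least 3 of them, with 1 point per gene and a bar at the list median. Medians range from 1.54 for macrophage markers to -1.26 for mitochondrially encoded genes and -2.25 for sex-linked genes.

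Camera called 19 of 31 lists as deposited, 9 higher and 10 lower than other genes. With an estimated correlation 1 list was called, and 7 of 100 splits of the libraries, the real one included, called at least 19 lists. Fetal and stress genes of cardiomyocytes were not called as deposited (adjusted p = 0.395), where 12 of 15 rose and 1 fell (13 adjusted over the list alone). They were called relative to the median gene (camera adjusted p = 0.0435, and adjusted p = 0.346 with an estimated correlation), where 8 rose and 3 fell (12 adjusted over the list alone). Of genes chosen after their values were seen, Ankrd1 rose by 2.26 and the fetal myosin gene Myh7 by 1.29 relative to the median gene, and the adult myosin gene Myh6 fell by 1.07. The remaining 7 gene lists were not called as deposited. Their first adjusted p is from camera as deposited, and their counts are relative to the median gene. Intercalated disc genes (camera adjusted p = 0.874) held 2 higher and 7 lower of 13 (9 adjusted over the list alone). The ATF4 response (adjusted p = 0.874) held 3 higher and 6 lower of 22 (9 adjusted over the list alone). Inflammatory mediators (adjusted p = 0.874) held 7 higher and 0 lower of 20 (7 adjusted over the list alone). Immediate early genes (adjusted p = 0.375) held 6 higher and 5 lower of 14 (13 adjusted over the list alone). Of 26 mitotic genes (adjusted p = 0.212) 0 were higher and 1 lower (1 adjusted over the list alone). Of 24 DNA replication genes (adjusted p = 0.202) 0 were higher and 7 lower (6 adjusted over the list alone). Camera called this list alone of the 7 relative to the median gene, as lower than other genes (adjusted p = 0.0296, and adjusted p = 0.608 with an estimated correlation). Glycolysis genes (adjusted p = 0.375) held 7 higher and 7 lower of 19 (14 adjusted over the list alone). As deposited, 11, 17, 14, 9, 21, 13 and 13 members of these lists rose and 0, 1, 0, 2, 0, 0 and 5 fell, in the order given. Of all 13282 tested genes, 10160 rose and 460 fell as deposited, and 2763 rose and 2766 fell relative to the median gene.

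Among the marker lists, macrophage markers rose in 17 of 17 tested members both as deposited and relative to the median gene (17 adjusted over the list alone). Their median was 1.54 relative to the median gene. As deposited, camera gave an adjusted p = 9.29e-07, and an adjusted p = 0.285 with an estimated correlation. The complement genes C1qa and C1qb rose from 14.7 ± 2.27 to 98.5 ± 13.3 TPM and from 11.3 ± 1.79 to 81.9 ± 13.6 TPM. Endothelial markers fell relative to the median gene in 13 of 15 members with 0 higher (14 adjusted over the list alone). As deposited, 3 rose and 1 fell (camera adjusted p = 0.00429; adjusted p = 0.571 with an estimated correlation), with Aplnr and Vwf at 0.25 and 0.14 relative to the median gene, neither called there. Erythroid markers were placed below other genes as deposited (camera adjusted p = 0.0127; adjusted p = 0.571 with an estimated correlation) and were not called relative to the median gene (adjusted p = 0.279). Of 5 members 0 were called (0 adjusted over the list alone), with log2 fold changes of 0.30 for Alas2 and 0.20 for Hba-a1. Camera values of the lists that follow are as deposited. Fibroblast markers (camera adjusted p = 0.904) held 5 higher and 5 lower of 12 relative to the median gene (10 adjusted over the list alone). Smooth muscle and pericyte markers (adjusted p = 0.296) held 2 and 5 of 11 (8 adjusted over the list alone), and atrial markers (adjusted p = 0.740) 3 and 2 of 8 (6 adjusted over the list alone). Of 6 skeletal muscle markers (adjusted p = 0.223), 0 were called relative to the median gene (0 adjusted over the list alone) and 2 were higher as deposited. Too few members were tested for camera in the lists of lymphocytes (1 of 14), neutrophils (2 of 10), epicardium (1 of 7), fat (1 of 8), lung epithelium (0 of 5) and Schwann cells and neurons (1 of 7). Relative to the median gene, the epicardial and the fat gene fell and none of the other genes in these lists was called.

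Sex-linked genes were lower in cKO in 2 of 4 tested members as deposited (0 adjusted over the list alone) and in 4 of 4 relative to the median gene (4 adjusted over the list alone). Camera placed them below other genes as deposited (adjusted p = 5.38e-06, and adjusted p = 0.248 with an estimated correlation) but did not call them relative to the median gene (adjusted p = 0.0881). Xist, transcribed from the inactive X chromosome, was at 54.1, 65.9 and 47.6 TPM in cKO replicates 1, 5 and 7 and under 1 TPM in the other 2 cKO and all 5 control libraries. Ddx3y and Eif2s3y on the Y chromosome had log2 fold changes of -2.28 and -3.01 as deposited (limma adjusted p = 0.0399 and 0.0365). With the 3 libraries left out, an alternative added after seeing the data, limma called 9250 genes as deposited, 8942 higher and 308 lower. Relative to the median gene it called 3477, of which 3382 were also called, in the same direction, with all 10 libraries. The libraries left in are part of those 10, so this overlap is no independent check.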

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

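The tests of the mitochondrial share and of liver RNA were chosen only after the result each measures was seen, and the epithelial test was extended to genes under the TPM filter after 1 of its 12 genes was found to pass it. Samples far from the others were sought in 192 groups of 5 values of named genes and library measures, and 10 stood apart, where chance gives about 9.6.

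Gsta1 reached 87.9 TPM in cKO replicate 7, against 42.1 to 54.8 in the other cKO libraries. Gsta3 reached 48.6 TPM in the same library, against 28.1 to 31.8. S100a1 was at 761 TPM there, against 510.5 to 573 in the others. In cKO replicate 6, Lrtm1 was at 11.3 TPM (6.74 to 7.59 in the others), Hrc at 79.0 (38.3 to 50.0), Sdha at 280.9 (240.5 to 249.6) and Ifit2 at 10.1 (12.5 to 13.4). In control replicate 8, Krt18 was at 4.02 TPM (3.04 to 3.30 in the others) and Irf7 at 1.25 (1.74 to 1.92). Rpl3l was at 10.6 TPM in control replicate 13 (14.5 to 15.6 in the others).

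Most genes were higher in cKO as deposited, with a median of 0.63. With TPM recomputed over nuclear protein-coding genes the median was still 0.18, and 0.16 to 0.21 with each library left out, which argues against the smaller mitochondrial share as the whole cause. With TPM recomputed without the 100 most abundant genes the median was 0.0635, so a smaller share of these genes in the cKO total is a candidate explanation for the shift. In a fixed total most genes can rise only if others take a smaller share, so this test had little room to fail. The 100 genes include the mitochondrially encoded mt-Atp8, so the tests overlap. Leaving out mitochondrially encoded genes alone gave a median of 0.27. Why the 100 genes take a smaller share in cKO hearts was not tested. A change in total RNA per cell stays open, because TPM cannot show it.

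The cKO group held 3 Xist-positive libraries and the control group none. Genes called from those 3 libraries against controls 4, 6 and 8 kept a median of 0.813 of their log2 fold change (quartiles 0.627 and 0.975) in the 2 Xist-negative cKO libraries against controls 9 and 13, which argues against sex as the cause of the calls as a whole. Within the cKO group, of the genes that passed the TPM filter, 5 differed between the Xist-positive and Xist-negative libraries: Ddx3y, Eif2s3y, Kdm5d, Uty and Gm43778. With 3 libraries against 2, smaller differences may have been missed, so this is not a count of all genes that differ by sex. Xist itself, on which the libraries were divided, did not pass the filter and so was not among the genes compared. With Ddx3y as a covariate over all 10 libraries, limma called 4066 genes relative to the median gene in place of 5529. As deposited it called 9746 in place of 10620. A share of sex in single genes stays open, since no control library was Xist-positive.

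The glutathione transferase genes Gsta1, Gsta2 and Gsta3 were among the 10 largest rises, together with Krt8 and Krt18. Liver transcripts had a median log2 fold change of -0.12 as deposited (13 of 17 genes tested, all 13 also present in these hearts above the filter), which argues against liver RNA in the cKO libraries. The 12 epithelial genes had a median log2 difference of 0.0061, but 11 of the 12 lay under the filter, where log2(TPM + 1) holds differences near 0. The largest rises were in Cldn4 (0.0362 TPM in control, 0.633 in cKO) and Elf3 (0.170 and 0.535), while Cldn7, Grhl2, Krt19 and Cdh16 were lower. The most abundant of the 12 averaged 2.25 TPM in cKO against 192 TPM for Krt18, which argues against epithelial cells. With 0 libraries from tamoxifen-treated animals with intact Chmp4b, tamoxifen or Cre activity in place of the loss of Chmp4b cannot be told apart from that loss, here and in every comparison of these groups.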

How the results depend on the processing

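Restricting TPM to nuclear protein-coding genes, leaving out the 100 most abundant genes, leaving out the 3 Xist-positive cKO libraries and the repeats relative to the median gene were chosen after seeing the data. No paired analysis was possible because no pairing of animals was given in the sources used here, and the groups share only 1 replicate number (6). Litter was not given either, so whether treatment followed litter is unknown. TPM keeps no depth, so counting error at low values could not be judged apart from the spread between libraries. No result here separates tamoxifen from the deletion.

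The number of called genes stayed within 1.5 times of 10620 under the other pseudocounts, filters, variance models, weights and covariate and without each library. It ranged from 7519 with a mean TPM of at least 5 to 11444 with no low-value filter. With the Ddx3y covariate it was 9746, with library weights 10736, and without each library 10230 to 10588. It was 5529 with median-of-ratios scaling, 5658 with quantile normalization, 6295 over nuclear protein-coding genes and 5836 without the 100 most abundant genes. In the same order, genes higher in cKO numbered 2763, 2856, 4566 and 3385 and genes lower 2766, 2802, 1729 and 2451. Without mitochondrially encoded genes 6193 were higher and 1477 lower, and with a mean TPM of at least 5, which tests fewer genes, 288 were lower. Genes changed by at least 2-fold numbered 832 (median of ratios), 795 (quantile), 1252 (mitochondrially encoded genes left out), 1014 (nuclear protein-coding) and 1283 (100 genes left out), and 3550 with a pseudocount of 0.1. The scalings and the genes left out reduce the general shift, whose median was 0.63 as deposited. It was 0.01 (median of ratios), 0.0018 (quantile), 0.27 (mitochondrially encoded genes left out), 0.18 (nuclear protein-coding) and 0.0635 (100 genes left out). Median-of-ratios and quantile scaling bring the median near 0 by construction, so their values say nothing about the shift. What lies behind the shift itself stays open. The smaller pseudocount enlarges folds of low genes by construction. With no model, 8560 genes had no overlap between groups. Relative to the median gene, the 5529 calls became 3477 without the 3 Xist-positive libraries, with fewer samples, and the 832 genes changed by at least 2-fold became 1266 with a pseudocount of 0.1.

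The 19 called lists became 1 with camera and an estimated correlation, and stayed between 15 and 19 under the other alternatives of the same test.

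The log2 difference of Chmp4b stayed below 0 in every alternative, from -0.21 to -0.38 without single libraries. Without any 1 cKO library, or without control replicate 6, 8 or 9, the difference was -0.21 to -0.30 and the exact permutation p lay between 0.0556 and 0.0952, with fewer samples. Without control replicate 4 the difference was -0.38 (exact permutation p = 0.00794). Without the 3 Xist-positive libraries the difference was -0.34 (exact permutation p = 0.190), with 2 cKO libraries left and so few possible splits. With all 10 libraries, the scalings and the runs with genes left out gave -0.73 to -1.01 (exact permutation p = 0.00794 in each).

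Of 93 other named genes, 69 kept direction and call throughout. Nexn went to -0.033 and Bin1 to -0.0548 with median-of-ratios scaling, and Bin1 to -0.0662 with quantile normalization. Dnm2 went to -0.12, -0.072 and -0.0605 and Cavin1 to -0.25, -0.20 and -0.19 with median of ratios, quantile and the 100 genes left out, and Cavin1 to -0.0721 over nuclear protein-coding genes. Without the 3 Xist-positive libraries only Y-bearing cKO libraries remained, and the fall of the Y-linked genes was lost. Eif2s3y was then at 0.76 and Ddx3y at 0.63, beside a median of 0.60 over all tested genes as deposited. The sex-linked list turned upward without a call (camera adjusted p = 0.661). Fry, which does not compare a list with other genes and so carries the general shift, gave upward directions for lists that camera placed lower. Its adjusted p values were 3.9e-05 for the ATF4, atrial and glycolysis lists, 0.0048 for DNA replication, 0.0818 for endothelial, 0.719 for erythroid and sarcomere, 0.000933 for immediate early genes, 0.0275 for mitotic cell cycle, 0.0429 for skeletal muscle, 0.0015 for smooth muscle and 0.0455 for T-tubule and dyad genes. Relative to the median gene, fry placed the T-tubule and dyad list downward (adjusted p = 1.8e-06), while the atrial list stayed upward (adjusted p = 0.00198).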

Other observations

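Beyond the glutathione transferases, the antioxidant defence genes Gclm, Nqo1 and Srxn1 were higher in cKO hearts. The genes in this paragraph were chosen after their values were seen. Gclm, a subunit of the enzyme that starts glutathione synthesis, rose from 9.07 ± 0.834 to 99.1 ± 12.7 TPM, the quinone reductase gene Nqo1 from 7.34 ± 1.17 to 113 ± 22.1 TPM and Srxn1 from 6.80 ± 1.87 to 93.9 ± 15.7 TPM (SD, n = 5 per group). The stress cytokine gene Gdf15 rose from 0.799 ± 0.325 to 29.9 ± 7.27 TPM and the chemokine gene Cxcl10 from 0.369 ± 0.121 to 22.3 ± 6.49 TPM. Ppargc1a, a coactivator of mitochondrial genes, fell from 43.9 ± 16.1 to 14.4 ± 1.14 TPM.

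The rises of the glutathione transferases, Gclm, Nqo1 and Srxn1 led to the hypothesis of a wider rise of NRF2 target genes, NRF2 being the transcription factor that induces many detoxification genes. A list of 28 further targets was written before their values were looked at, leaving out those already seen among the largest rises, and shares Slc7a11 with the ATF4 list. Of the 26 tested, 26 rose as deposited and 24 rose relative to the median gene, with 0 lower and a median of 1.18. Macrophage markers rose in the same hearts in 17 of 17 members, with a median of 1.54 relative to the median gene. Camera, a test across all genes, gave p = 6.43e-09 for the list as deposited, but p = 0.113 with an estimated correlation (no exact permutation test was run). A wider rise of NRF2 targets may therefore underlie the pattern, with a test that depends on how correlation between genes is treated. Whether it follows from the loss of Chmp4b, from tamoxifen or from a change in cell types was not tested.

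Other splits of the libraries were drawn, 100 of the 126 splits into 5 and 5, the real one included. The real split called 10620 genes as deposited, 2317 changed by at least 2-fold and 5529 relative to the median gene. No other split called more than 2 in any of the 3, so 1 of 100 splits, the real one, reached each real count. This is the smallest share that 100 splits allow, so it does not exclude chance. Every other split mixes cKO and control libraries within each group. A large difference between cKO and control then widens the spread within groups, which keeps the counts of the other splits low. The splits also cannot tell treatment from sex or litter. For gene lists, 7 of 100 splits called at least as many lists as the 19 of the real split, with up to 20 in another split and a median of 12. Splits that mix the groups unevenly can still carry part of a group difference into the list test, and lists were split as deposited only. The splits therefore cannot show what camera would call without a group difference. No conclusion is drawn from the number of lists called with the preset correlation. The counts of called genes within each list rest on the gene tests and are to be read against all 13282 tested genes. Of these, 10160 rose and 460 fell as deposited, and 2763 rose and 2766 fell relative to the median gene. A list whose share of calls lies near theirs does not stand apart from other genes.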
